A study of Mus musculus with 6 samples.

How the data were processed

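Prefrontal cortex of 3 BTBR and 3 C57BL/6J male mice was dissected fresh and frozen, and RNA was purified on columns, per the labels' protocols. Columns of the standard kind recover long RNA better than short RNA, so small RNA yield can vary between samples. RNA integrity numbers were 9, and 100 ng of total RNA per sample went through reverse transcription and pre-amplification, per the labels' protocols. The product was loaded on the OpenArray rodent panel and run on a real-time PCR instrument, per the labels' protocols. Which samples shared an array is not given in the sources used here, so if the strains were run on separate arrays, a difference between arrays cannot be separated from one between strains.

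The raw table holds cycle thresholds for 750 miRNA assays (377 in pool A and 373 in pool B) and 96 control lines, that is 16 spots each of U6 rRNA, snoRNA135, snoRNA202, U87, Y1 and the plant control ath-miR159a. Within each sample the 16 values of a control are sorted, so a line is not the same spot across samples. A value of 40 was read as undetermined. The instrument software and its threshold settings are not given in the sources used here. A threshold has no counting depth: precision is limited by 1 PCR per assay and 3 mice per strain. The number of assays detected per sample ranged from 296 to 409 of 750.

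The authors' normalized table holds quantile-normalized cycle thresholds of 306 assays, per the file headers, with 251 cells at 40 (141 in C57BL/6J and 110 in BTBR). Its other steps are not given in the sources used here and were worked out from both tables. Raw values under 10 were set to 40, assays detected in at least 3 of the 6 samples were kept (340), and the samples were given common quantiles with 40 entering as a value. Normalized values above 29.19 were then set to 40, and assays with at least 3 detected samples were kept again. These steps gave the deposited values with a largest difference of 3.33e-09 cycles, and 0 cells differed in being at 40. Because 40 takes part in the ranking, a sample with more undetermined cells gets lower thresholds for the assays it detects. The authors' deposited fold table gives, per its file header, a ratio of BTBR to C57BL/6J, its log2 value with the sign turned (a difference of mean thresholds), a test statistic (a score) and a p-value with its adjusted p-value. The means in the authors' deposited table keep 40 as a value, and the variant of the authors' test and the method of adjustment are not given in the sources used here.

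For the strain comparison, the authors' normalized thresholds were multiplied by -1 to give a log2 scale on which higher means more miRNA, taking 1 cycle as a 2-fold difference, and 40 was treated as missing, which leaves out late readings as well as undetermined ones (83 cells at 40 had a raw number). Assays with at least 2 detected values in each strain (231) were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with strain as the single term and Benjamini-Hochberg adjustment over the assays tested, at a threshold of 0.05. Changes are BTBR minus C57BL/6J. Lists of miRNAs (15 in all) were fixed before the data were examined: neuron-, oligodendrocyte- and astrocyte-enriched, microglial and other immune, endothelial and mural, red blood cell, choroid plexus, the Dlk1-Dio3, Sfmbt2 and X-linked clusters, the miR-17 group, let-7, miR-29 and miR-30, activity-regulated, and miRNAs named in autism studies. Names were matched without species prefix and arm, and lists overlap. The 11 lists with at least 3 members measured in all 6 samples were tested with limma's camera (preset correlation 0.01), which compares a list with the other assays, and with fry, which asks whether a list moves on balance one way. The red blood cell, oligodendrocyte, Sfmbt2 and X-linked lists had too few such members and are described by their members alone. Counts of detected assays and control values were compared with exact permutation tests, two-sided, whose smallest p is 0.1.

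Named assays were chosen by a rule fixed before the data were examined. It takes the 12 largest falls past the threshold that went the same way in every BTBR sample, the 8 smallest p among higher values since fewer than 5 passed, and the members of each list that passed together with up to 4 of its largest changes. It also takes up to 5 assays detected in 1 strain only, by mean level, and all endogenous controls. The assay hsa-miR-140-3p, the list members detected in 1 strain only, hsa-miR-92, the 3 assays detected in C57BL/6J only and the 4 with a second assay were named outside this rule, after their values were seen.

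The assay test was checked on simulated data with the 231 assays and their spread, 60 of them changed in each of 50 runs. It recovered 15.3% of changes of 1 cycle, 56.3% of 2 cycles and 76.2% of 3 cycles, and 3.84% of calls were false. For the list test, on 189 assays, a shift of 1 cycle in the Dlk1-Dio3 list was found in 100% of 50 runs and 0% of unchanged lists were called. In both checks the noise was drawn for each assay independently, and only this list, the longest, was shifted. The runs therefore do not show how the tests do with correlated assays or with a shift of the whole panel, or how often a shift in a shorter list is found.

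Alternatives tried were other normalizations of the raw thresholds (global mean, global median, U6 rRNA, the other controls, quantiles of detected values), other detection filters, raw thresholds above 28 taken as undetected, undetermined values set 1 cycle above the highest detected value, other variance models, the replicate number as a block, an adjusted p of 0.1 and leaving out each sample. Added after seeing the data were the global mean over the cells of the normalized table, centring of the authors' values on sample medians, the median of the U6 rRNA spots, the 4 earliest spots of the 5 controls, the global mean within each pool, and the rebuilt normalization with late readings kept. Endogenous and plant controls were not tested among the miRNAs, and assays outside the authors' normalized table entered no test.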

Results

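MicroRNA (miRNA) levels were measured in the prefrontal cortex of 6 male mice aged 5 months, 3 of the inbred strain BTBR and 3 of the inbred strain C57BL/6J. BTBR mice are widely used as a model of autism-like behaviour, and C57BL/6J served as the control strain. Each mouse gave 1 sample, so the replicates were separate animals. The TaqMan OpenArray rodent panel holds 750 miRNA assays, each run once per sample, and 5 endogenous small RNA controls with 16 spots each. The readout was the cycle threshold, the PCR cycle at which an assay's signal crosses a set level, so that a higher value stands for less RNA. The instrument's value of 40 was read as undetermined. Assay names carry the species of the design (hsa, mmu or rno), and # marks the less abundant strand of a hairpin. The letter A or B in brackets is the suffix of the assay's identifier, here called its pool. The files gave no genome positions, and none are reported.

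The question was which miRNAs differ in level between BTBR and C57BL/6J prefrontal cortex. On the authors' normalized values, hsa-miR-199a-3p (assay 002304), which shares a transcript with miR-214, had a threshold of 24.9 ± 0.0977 cycles in C57BL/6J and 27.83 ± 0.263 in BTBR (SD, n = 3 each). That was 7.59-fold less in BTBR (log2 change -2.92, standard error 0.28, limma adjusted p = 0.0118), the smallest adjusted p of the 231 assays tested. Its raw thresholds were 25.88 ± 0.113 and 26.16 ± 0.662 cycles, so most of that difference is not in the raw values. Folds on the authors' values include a shift of the whole panel, described below. The assay mmu-miR-770-5p (002608), from an intron of the imprinted gene Meg3, went from 23.66 ± 0.351 to 26.98 ± 0.58 cycles, 9.94-fold less (log2 change -3.31, standard error 0.41, limma adjusted p = 0.0233). The largest fall was that of hsa-miR-32 (002109), with 17.87 ± 0.817 cycles in C57BL/6J and 23.26 ± 0.82 in BTBR (SD, n = 2 samples each in the normalized table), a log2 change of -5.39 with a standard error of 0.69 (limma adjusted p = 0.0298). In the other direction, mmu-miR-140 (001187), best known from cartilage, stood at 25.16 ± 0.466 cycles in C57BL/6J and 22.46 ± 1.37 in BTBR (SD, n = 3 each), 6.52-fold more in BTBR (log2 change 2.71, standard error 0.73, limma adjusted p = 0.036). The assay of its other arm, hsa-miR-140-3p, looked up after these values were seen, had the opposite sign and did not pass (log2 change -0.90, standard error 0.38, limma adjusted p = 0.109). It lay within its standard error of the median change of all tested assays, -1.13, so it did not stand apart from the panel. The change of mmu-miR-140 lay 3.83 above that median.

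Of the 231 assays, 85 passed an adjusted p of 0.05 in limma, 3 higher and 82 lower in BTBR, and 113 had an unadjusted p under 0.05. After miR-32, the largest falls were those of hsa-miR-381 (log2 change -3.74), hsa-miR-369-5p (-3.52), hsa-miR-189 (-3.43) and mmu-miR-770-5p. Next came mmu-miR-669a (-3.14), rno-miR-29c# (-3.10), hsa-miR-338-3p (-3.08), rno-miR-598-5p (-3.01), miR-199a-3p, mmu-miR-467c (-2.91) and rno-miR-148b-5p (-2.89). Of these, miR-338-3p had 2 BTBR values and miR-598-5p 2 C57BL/6J values, its other C57BL/6J sample being undetermined. The authors' deposited table, which keeps 40 as a value, gives miR-598-5p as 5.90-fold higher in BTBR. Beside miR-140, the rises were MMU-MIR-1274A, with a log2 change of 3.94 (standard error 0.98), and HSA-MIR-421, with 1.61 (standard error 0.44), each with only 2 BTBR values in the normalized table. Their readings in BTBR replicate 3, at raw thresholds of 28.54 cycles for HSA-MIR-421 and 27.54 for MMU-MIR-1274A, stand at 40 there and were near the C57BL/6J raw means of 28.22 and 27.37. The next smallest p among higher values belonged to assays that did not pass. These were MMU-MIR-1960 with a log2 change of 6.28 (standard error 1.66), hsa-miR-181a with 5.05 (1.77), mmu-miR-182 with 3.42 (1.23), hsa-let-7c with 4.18 (1.73) and hsa-miR-484 with 1.67 (0.77). Among the 85 assays that passed, 7 had a reading in the raw table that stands at 40 in the normalized one. With the late ones of these kept, an alternative chosen after seeing the data, 83 of the 85 differed from the C57BL/6J mean in the same direction in every BTBR sample, all but HSA-MIR-421 and MMU-MIR-1274A. In that fit 84 assays passed (2 higher, 82 lower), 70 of them among the 85, with HSA-MIR-421 at -0.59 (limma adjusted p = 0.807), MMU-MIR-1274A at 1.10 (0.754), miR-32 at -7.79 (0.0776) and miR-338-3p at -5.04 (0.0757) not among them.

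**Figure D1:**
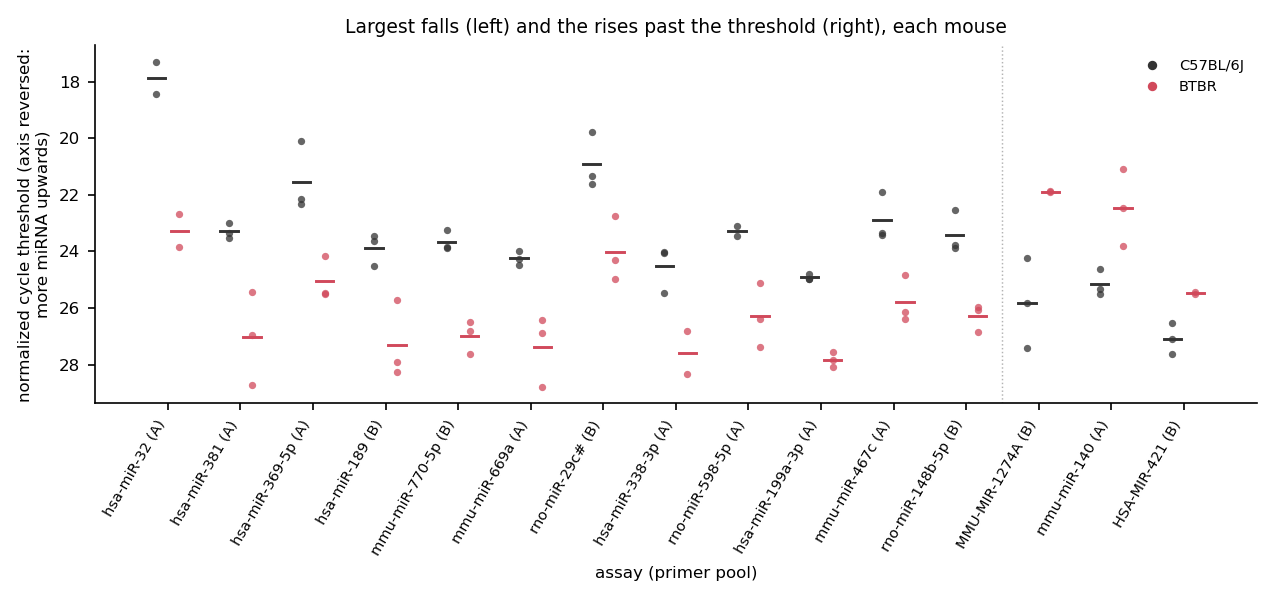
Normalized cycle threshold (vertical axis, reversed so that more miRNA lies upwards) of each mouse with a value in the normalized table, for the 12 largest falls (left of the dotted line) and the 3 rises (right). Points are mice and bars are group means, black for C57BL/6J and red for BTBR. For miR-199a-3p the group means are 24.9 and 27.83 cycles.

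These calls lay on a shift of the whole panel. The median log2 change of the 231 assays was -1.13, and 190 of them were negative. Over the 189 tested assays with 6 values, the median change was -1.11 on the authors' values and -0.05 on the raw thresholds. When raw thresholds of the same cells were centred on each sample's mean over the assays detected throughout (the global mean), 1 assay passed in limma, HSA-MIR-421, which was higher in BTBR (log2 change 3.68, adjusted p = 0.026) with 2 BTBR values, the one left out being at the C57BL/6J level, 0 were lower, and 69 had an unadjusted p under 0.05. Of the 82 assays that fell on the authors' values, 75 had a negative change on the global mean scale too and 7 a positive one. Relative to the median of the panel, the change of miR-199a-3p was -1.80, that of miR-770-5p -2.19 and that of miR-32 -4.27. On the global mean scale the corresponding values were -0.46, -1.39 and -4.07. The values of miR-140 (4.24) and MMU-MIR-1274A (6.20) were larger there than on the authors' scale, with adjusted p of 0.0737 and 0.0773. Without BTBR replicate 1 or without C57BL/6J replicate 3, 0 assays passed on the authors' values. BTBR replicate 3 stood apart from its group: over the assays with 6 values it correlated more with the C57BL/6J samples (Pearson r = 0.945, 0.966 and 0.951) than with BTBR replicates 1 and 2 (0.938 and 0.918), and without it 101 assays passed, 13 higher and 88 lower.

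**Figure D2:**
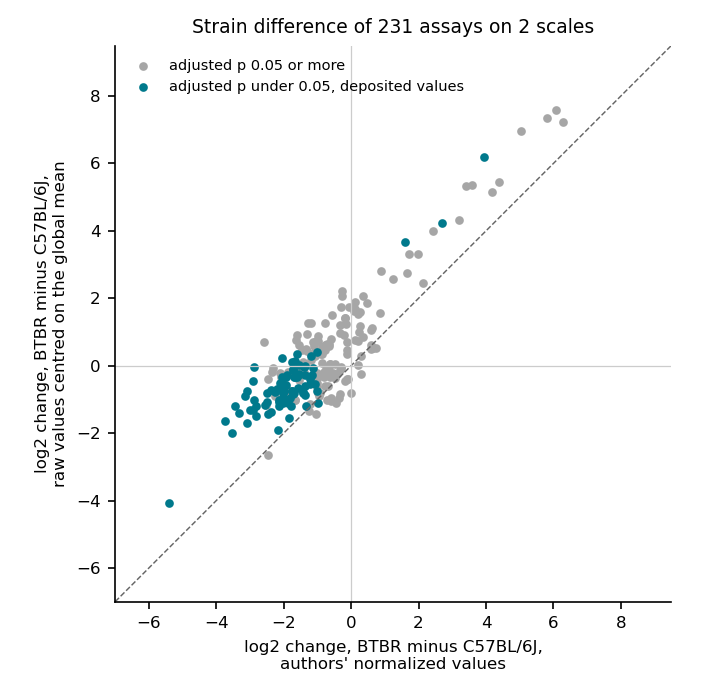
Log2 change between the strains for the 231 tested assays, from the authors' normalized values (horizontal axis) and from raw thresholds centred on the global mean (vertical axis). Teal points are the 85 assays past an adjusted p of 0.05 on the authors' values, grey points the others, and the dashed line marks equal values. Most points lie above that line, and the median on the horizontal axis is -1.13.

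The Dlk1-Dio3 imprinted cluster, a large group of miRNAs expressed from the maternal chromosome and abundant in brain, held the most assays that fell and the most that were tested. Its share of falls was close to that of the whole panel, where 82 of 231 assays fell. Of its 39 tested assays, 15 fell, 0 rose and 24 did not pass, with the same 15 falls when adjusted over the list alone. That count was 4 without BTBR replicate 1, 8 without C57BL/6J replicate 3 or BTBR replicate 2, 9 without C57BL/6J replicate 2, and 1 with the authors' values centred on sample medians. Besides miR-381, miR-369-5p and miR-770-5p, these were mmu-miR-770-3p (log2 change -2.89), hsa-miR-409-5p (-2.56), mmu-miR-434-5p (-2.47), mmu-miR-380-5p (-2.38), mmu-miR-544 (-2.06), hsa-miR-543 (-1.87), hsa-miR-487b (-1.84), mmu-miR-376a (-1.80), mmu-miR-541 (-1.72), hsa-miR-323-3p (-1.59), hsa-miR-370 (-1.44) and hsa-miR-539 (-1.06). On the global mean scale, 0 of the 39 passed over all assays, while 13 were lower and 3 higher when adjusted over the list alone. Of the 15 that fell, 11 were among those 13, including miR-369-5p (-1.98), miR-381 (-1.64), miR-487b (-1.56), miR-434-5p (-1.42) and miR-380-5p (-1.37). The other 4 were at -0.03 (miR-770-3p), -0.11 (miR-541), -0.29 (miR-323-3p) and -0.54 (miR-539) there. A further 5 assays of the cluster, which the test could not take, are not in these counts: mmu-miR-337-5p, mmu-miR-668, mmu-miR-329, rno-miR-381 and mmu-miR-487b were detected in all BTBR and no C57BL/6J samples. No direction of change follows from an undetermined assay, and miR-381 and miR-487b each have another assay among the 15. As a set, the cluster did not stand apart from the other assays (limma camera adjusted p = 0.22, and 0.867 with an estimated correlation). Its median lay 0.05 above that of all assays with 6 values while the test pointed down, and its shift on the global mean scale was -0.09. On raw thresholds with all detected cells, 46 members were tested, and the count adjusted over the list alone depended on the scaling. It was 0 with the global mean, the global median, the mean of detected control spots (U6 rRNA or the others) and the 4 earliest control spots. With the global mean within each pool it was 13 lower and 2 higher. The median of the U6 rRNA spots gave 7 lower, and quantiles of detected values gave 3 lower.

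Among miRNAs enriched in brain cell types, 5 of 25 neuron-enriched assays fell and 0 rose: both miR-770 arms, miR-376a, hsa-miR-184 (log2 change -1.74) and hsa-miR-129 (-1.67). The assay for mmu-miR-124a, from the most neuron-specific miRNA of the list, had a log2 change of 1.97 with a standard error of 0.95 and did not pass. Adjusted over the list alone, 4 fell, against 1 on the global mean scale, hsa-miR-124# was detected only in C57BL/6J, and the camera adjusted p of the neuron list was 0.794 (0.867 with an estimated correlation). Of 4 oligodendrocyte-enriched assays, miR-338-3p fell (also 1 adjusted over the list alone, but 0 on the global mean scale), and hsa-miR-23a was detected only in C57BL/6J. The assays hsa-miR-219 (-2.36, standard error 1.06) and hsa-miR-219-2-3p (-1.54, standard error 0.69), from a miRNA that drives oligodendrocyte maturation, did not pass, and hsa-miR-138, whose normalized values are all the lowest the table keeps and so carry no difference, had a change of -0.81 (standard error 0.31) on the global mean scale. Of 4 astrocyte-enriched assays, 3 fell, miR-199a-3p, hsa-miR-214 (-2.05) and mmu-miR-31# (-1.18), and hsa-miR-145 had a change of -2.47 (standard error 0.77, limma adjusted p = 0.0596). On the global mean scale miR-31# had the opposite sign, with 0.30. Adjusted over the list alone, 4 of the 4 fell, but 1 on the global mean scale, where miR-199a-3p was at -0.46 and miR-214 at -0.50. The assays mmu-miR-31, the other strand of miR-31#, and hsa-miR-143 of this list, outside the test, were detected in all BTBR and no C57BL/6J samples. The astrocyte list had a camera p of 0.0459, which became 0.22 after adjustment and 0.659 with an estimated correlation.

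Among the lists of cells other than neurons and glia, 1 of 6 microglial, myeloid or lymphoid assays fell, hsa-miR-146a (log2 change -0.99), a brake on innate immune signalling. The assay hsa-miR-142-3p, made in blood-derived cells, had a change of -2.14 (standard error 0.62, limma adjusted p = 0.051), RNO-MIR-146B one of -0.74 (0.32) and hsa-miR-150 one of -0.72 (0.40). The list lay 0.38 above all assays on the authors' scale but 0.33 below them on the global mean scale, where its shift was -0.33 (camera adjusted p = 0.794 on the authors' scale, 0.867 with an estimated correlation). Adjusted over the list alone, 0 fell on either scale. In the raw values miR-155 was detected only in BTBR, at 6.71 cycles, a value that the authors' steps as rebuilt treat as undetermined. Of 8 endothelial and mural assays, mmu-miR-322 (-2.25) and mmu-miR-503# (-1.73) fell, and hsa-miR-139-5p had a change of 0.58 (standard error 0.48). The erythroid mmu-miR-451, the 1 tested assay of the red blood cell list, differed by -0.21 (standard error 0.33) on the authors' scale and by 0.90 (0.36) on the global mean scale, where it passed only when adjusted over the list alone, and hsa-miR-486 of that list was detected only in BTBR. Of 6 choroid plexus assays, 0 passed, with changes of 3.42 for miR-182, -1.88 (standard error 0.67) for rno-miR-204#, 1.25 (1.54) for hsa-miR-200c and -0.78 (2.17) for hsa-miR-183, which was at 0.62 on the global mean scale. Relative to all assays, the endothelial and mural list lay 1.07 higher and the choroid plexus list 1.02 higher, with camera adjusted p of 0.165 and 0.22, each 0.659 with an estimated correlation, and 0 assays of either passed when adjusted over the list alone on the authors' scale. On the global mean scale that count was 2 lower for the endothelial and mural list and 1 higher for the choroid plexus list. Detected only in BTBR were miR-143 of the former and mmu-miR-34b-3p and hsa-miR-200b of the latter.

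In the remaining lists, 3 of 5 assays of the miR-17 group of clusters fell, hsa-miR-93# (log2 change -1.99), hsa-miR-20b (-1.70) and hsa-miR-19b (-1.38), and mmu-miR-106a had a change of -0.62 (standard error 0.31), but 0.04 on the global mean scale. Adjusted over the list alone, the same 3 fell, but 1 on the global mean scale (camera adjusted p = 0.668, 0.867 with an estimated correlation). As many members, hsa-miR-20a, hsa-miR-106b and hsa-miR-18a, and hsa-miR-92, which the match by name left out of the list, were detected in all BTBR and no C57BL/6J samples. Of 9 assays of the miR-29 and miR-30 families, 5 fell: miR-29c#, hsa-miR-29b-2# (-1.60, but 0.34 on the global mean scale), hsa-miR-30d (-1.44), hsa-miR-30e (-1.38) and hsa-miR-30a-5p (-1.01). The assay hsa-miR-30b of that list had a change of 5.81 with a standard error of 3.91, with normalized thresholds of 17.41 and 16.19 cycles in BTBR replicates 1 and 2 but 28.25 in BTBR replicate 3 (C57BL/6J 26.95 and 25.91). Adjusted over the list alone, 5 fell, but 0 on the global mean scale (camera adjusted p = 0.668, 0.867 with an estimated correlation). Of 7 let-7 assays, mmu-let-7a# fell (-1.61), while let-7c and hsa-let-7e (4.38, standard error 2.06; 18.56 and 17.99 cycles in BTBR replicates 1 and 2 but 25.00 in replicate 3) lay higher and hsa-let-7i lower (-0.92, standard error 0.33), none past the threshold. The let-7 median was -0.62, its mean 0.59, and the camera test pointed up relative to the other assays (adjusted p = 0.22, 0.659 with an estimated correlation), while the shift on the global mean scale was -0.10. Adjusted over the list alone, 1 fell, but 0 on the global mean scale, and let-7b and hsa-let-7f were detected only in BTBR. Both tested assays of the cluster in an intron of Sfmbt2, miR-669a and miR-467c, fell, as did mmu-miR-547 (-1.67), the 1 tested member of the X-linked testis-type cluster, which was at 0.13 on the global mean scale. With late readings kept, mmu-miR-547 did not pass (log2 change -2.96, standard error 1.17, limma adjusted p = 0.0958). Adjusted over each list alone, the same 2 and 1 fell, with 2 and 0 on the global mean scale, and mmu-miR-467a of the Sfmbt2 cluster was detected only in BTBR. Of 13 activity-regulated assays, miR-184 and miR-146a fell, and hsa-miR-26b# had a change of -1.18 (standard error 0.61), but 1.26 (0.68) on the global mean scale. That list lay 0.61 above all assays on the authors' scale and at -0.08 on the global mean scale (camera adjusted p = 0.22, 0.659 with an estimated correlation), and 0 fell on either scale when adjusted over the list alone. Of 19 assays of miRNAs named in studies of autism, 9 fell, against 82 of 231 over the whole panel. Among them were miR-338-3p, miR-598-5p (with 2 C57BL/6J values), miR-148b-5p, mmu-miR-598 (-2.14), hsa-miR-27a (-2.03) and hsa-miR-107 (-2.01). The other 3 were miR-93#, miR-539 and miR-146a, and 10 fell when adjusted over the list alone, but 0 on the global mean scale (camera adjusted p = 0.794, 0.867 with an estimated correlation). Of that list, miR-155 (at the early raw value given above), hsa-miR-652, hsa-miR-103 and miR-106b were detected only in BTBR and miR-23a only in C57BL/6J. In limma's camera test, 0 of the 11 lists with at least 3 complete members passed, with unadjusted p under 0.05 for the endothelial and mural list (0.015) and the astrocyte list only. The fry test, which the shift of the whole panel enters, gave an unadjusted p under 0.05 for 8 of the 11.

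The next question was whether the strains differed in which miRNAs were detected. In C57BL/6J 306, 302 and 296 of the 750 assays gave a value, and in BTBR 360, 409 and 352. The means were 301 ± 5.03 and 374 ± 30.9 (SD, n = 3 each, exact permutation p = 0.1, two-sided, the smallest p that 3 against 3 samples allow). The difference lay in pool A, with 178 ± 2.08 against 235 ± 17.9 detected assays (exact permutation p = 0.1), and was within the spread in pool B, with 124 ± 5.69 against 139 ± 24.5 (exact permutation p = 0.4). In raw thresholds, on which detection in 1 strain only rests throughout (all 3 samples of it and 0 of the other), 30 assays were detected in all BTBR samples and in no C57BL/6J sample, 28 of them in pool A, and 3 in all C57BL/6J samples and in no BTBR sample. The assays of the first kind with the earliest thresholds were mmu-miR-155, an immune regulator, at 6.71 ± 0.259 cycles, mmu-miR-31 at 10.12 ± 1.24, hsa-miR-328 at 12.56 ± 0.428, hsa-let-7b at 14.19 ± 0.768 and hsa-miR-342-3p at 14.89 ± 1.76 (SD, n = 3 BTBR). Of these, miR-155 and miR-31 are not in the authors' normalized table, whose steps as rebuilt treat raw values under 10, such as those of miR-155, as undetermined. The 3 assays of the second kind were hsa-miR-124# at 19.37 ± 4.96 cycles, hsa-miR-23a at 21.16 ± 0.965 and rno-miR-24-1# at 22.62 ± 0.54 (SD, n = 3 C57BL/6J). Of the 30, 4 had a second assay of the same miRNA on the panel that was detected in all BTBR samples (miR-143, miR-190b, miR-381 and miR-487b), and all 4 second assays were detected in the 3 C57BL/6J samples.

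The endogenous controls asked whether reference RNAs themselves differed. The median of the 16 spots was earlier in BTBR for U6 rRNA (14.0 ± 0.345 against 16.01 ± 0.904 cycles), snoRNA135 (19.74 ± 0.118 against 20.83 ± 0.593), snoRNA202 (13.01 ± 0.323 against 14.41 ± 0.773), U87 (21.31 ± 0.447 against 24.36 ± 0.596) and Y1 (15.9 ± 0.471 against 19.78 ± 0.557; SD, n = 3 each). Each of these had an exact permutation p of 0.1. The 4 earliest spots of each control differed less, by -0.07 cycles for U6 rRNA, -0.78 for snoRNA135, -0.05 for snoRNA202, -0.39 for U87 and -0.24 for Y1 (BTBR minus C57BL/6J, exact permutation p from 0.3 to 0.8). Of 240 control spots per strain, 57 were undetermined in C57BL/6J (23.8%) and 3 in BTBR (1.25%), or 19 ± 2 and 1 ± 1 of 80 per sample (SD, n = 3 each, exact permutation p = 0.1). The plant control ath-miR159a was undetermined in every spot of every sample.

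**Figure D3:**
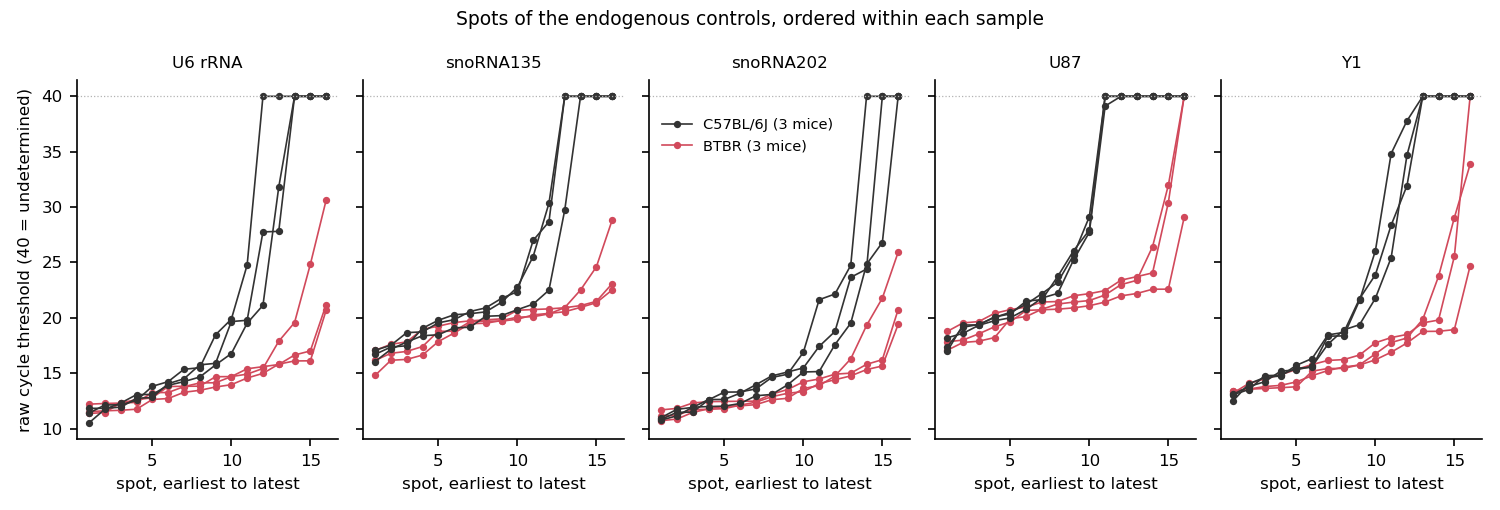
Raw cycle thresholds (vertical axis, 40 for undetermined) of the 16 spots of each endogenous control, ordered from earliest to latest within each sample (horizontal axis). Lines join the spots of a sample, black for C57BL/6J and red for BTBR. The earliest spots overlap between the strains, and the latest of the C57BL/6J samples reach 40, with 57 undetermined spots against 3.

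The authors' deposited table gives a fold change for each assay of their normalized table. Of its 48 assays with an adjusted p under 0.05, 34 had a group mean of 40 in the authors' deposited table, 25 of them in C57BL/6J and 9 in BTBR. All 25 had no raw reading in C57BL/6J, whereas of the 9, 2 had no raw reading in BTBR and 7 had late readings in at least 1 BTBR sample that stand at 40 in the normalized table. The other 14 were all lower in BTBR in the authors' deposited table, and all 14 were among the 82 that fell in limma, where values of 40 were left out. Across the 231 assays with both values, the log2 changes of the authors' deposited table and of the limma fit had the same sign for 221, with Pearson r = 0.683 and Spearman rho = 0.82. These are correlations across assays, which are not independent replicates. Over the 189 assays with 6 detected values, r was 1, which was fixed in advance, since both changes are there the same difference of group means. The 14 shared calls rest on the same values as well.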

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

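All tests in this part were chosen after the results were seen. In 444 assays outside the authors' normalized table, which entered no comparison, 9 were detected in all 6 samples, and 2 of them were earlier in every BTBR sample than in every C57BL/6J sample, a separation that, counting both directions, chance gives 1 assay in 10. Raw thresholds of mmu-miR-582-5p were 4.07 cycles earlier in BTBR (28.46 ± 1.46 against 32.53 ± 0.498), and those of mmu-miR-666, a Dlk1-Dio3 member, 3.06 cycles earlier (27.99 ± 1.29 against 31.05 ± 0.135; SD, n = 3 each). Outside that table, 58 assays gave a value in 2 or 3 BTBR samples and in no C57BL/6J sample, against 7 with the strains exchanged.

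The first pattern weighed is the set of 30 assays detected in all BTBR and in no C57BL/6J samples, where 1.02 would be expected if the C57BL/6J samples lost assays independently of each other. A level below the detection limit in C57BL/6J stays open, since the median of 18.6 cycles against 21.9 for the assays detected in all 6 samples was measured in BTBR and says only that the strain difference would have to be large. Absence of the miRNA from C57BL/6J cortex, or such a low level, is argued against for 1 miRNA, miR-487b, whose second assay was within 1 cycle of the first in BTBR (17.9 against 17.6) and read 16.5 cycles in C57BL/6J. It stays open for 26 without a second assay. For 3 others the second assay gave values in all C57BL/6J samples. It read far later than the first in BTBR (26.3 against 22.1 cycles for miR-143, 30.2 against 20.1 for miR-190b and 25.5 against 19.6 for miR-381). In C57BL/6J these second assays averaged 25.3, 28.5 and 24.1 cycles in that order, none later than in BTBR. That argues against absence or a very low level only if both assays read the same miRNA, which such unlike levels leave unsure. Failed spots on the C57BL/6J arrays remain an open candidate explanation, with 57 undetermined control spots in C57BL/6J against 3 in BTBR. All control lines carry the suffix of pool B while 28 of the 30 assays are in pool A. The control values are sorted within each sample, so whether a spot belongs to pool A or B cannot be told. That suffix therefore does not count for or against failed spots.

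The second pattern is that 82 of the 85 assays past the threshold were lower in BTBR. When the BTBR samples were compared with copies of themselves in which the cells undetermined in C57BL/6J were set to 40, the authors' steps gave a median log2 change of -1.04, against 0 for unmasked copies and -1.13 between the strains. The copies keep the undetermined cells of BTBR and gain those of C57BL/6J. The sign was thus fixed in advance, and the excess of such cells can be larger than between the real samples. Over the 189 tested assays with 6 values, the median change was -0.05 on raw thresholds and -1.11 on the authors' values. Most of the shift therefore arose in the authors' steps. Quantiles of detected values, with 40 left out, gave a median of -0.26 over 273 assays. Undetermined cells that enter the quantile normalization may thus account for much of the shift, in a share that the copies cannot give. A lower miRNA content in BTBR stays open. Common quantiles take out a difference shared by all assays, so the shift on the authors' values is no sign of such a content. The median change of raw thresholds over the tested assays was -0.0267. Scaling to the controls gave from -2.01 (median of the U6 rRNA spots) to -0.32 (the 4 earliest spots of the 5 controls), and the control spots differ between the strains as well. The 10 splits of the 6 samples are too few for a share under 0.05, with 85 assays in the real split, reached by 1 split, and 3 as the highest of the others. For lists the real split gave 0, which all 10 splits reach by definition, so the splits decide nothing there. The highest of the others was 1.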

How the results depend on the processing

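The count of 85 assays (3 higher, 82 lower) depended on the scaling, and scalings named as added were chosen after seeing the data. On raw thresholds, 0 assays passed after centring on the global mean, the global median or quantiles of detected values, 0 after scaling to the controls other than U6 rRNA, and 1 (1 higher, 0 lower) after scaling to U6 rRNA, with 69 to 103 at an unadjusted p under 0.05 in limma. The median log2 change moved from -1.13 to -0.36, -0.60, -0.26 and -1.33 in the first 4, in that order. Among added scalings, the global mean on the cells of the normalized table gave 1 (1 higher, 0 lower; median -0.18), centring the authors' values on sample medians 2 (1 higher, 1 lower; median 0.0478), and the median of U6 rRNA spots, the 4 earliest control spots and the global mean within each pool 0 each, with medians of -2.01, -0.32 and -0.30. Also added, the fit with late readings kept gave 84 (2 higher, 82 lower; median -1.24), 70 of them among the 85. The cause of the difference between scalings is weighed with the 82 lower assays.

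With undetermined values set above the highest detected value, the rebuilt normalization was run anew and left no missing cells. Of 306 assays then tested, 94 passed (26 higher, 68 lower), 53 of them among the 85. Assays undetermined in all samples of 1 strain entered that fit. On the authors' values, 19 assays (0 higher, 19 lower) passed without moderation of the variance, 1 was higher among assays detected in all 6 samples, and 6 were higher at an adjusted p of 0.1. Leaving out a sample gave from 0 to 101 assays, 0 to 13 higher and 0 to 88 lower, with 0 without C57BL/6J replicate 3 or BTBR replicate 1, 3 without C57BL/6J replicate 2, 8 without BTBR replicate 2, 64 without C57BL/6J replicate 1 and 101 (13 higher, 88 lower) without BTBR replicate 3. Each of these fits had 1 sample fewer, so the smaller number alone does not account for the range, which depended on the sample left out. The cause was not tested. With the replicate number as a block, 49 assays passed (1 higher, 48 lower), 43 of them among the 85. The deviations of same-numbered samples correlated at 0.083, 0.421 and -0.00132, and not every sample correlated best with its own number. Pairing by number was therefore not shown, and so few values cannot exclude it.

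Among the named assays that had passed, miR-31# turned to 0.12 with the global mean, 0.30 on the normalized cells, 0.17 with the earliest control spots and 0.28 within pools, and hsa-miR-29b-2# (B) to 0.17, 0.34, 0.21 and 0.32 in the same order and 0.0243 with quantiles. Mmu-miR-547 turned to 0.13 on the normalized cells, and miR-146a, miR-539 and miR-30a-5p to 0.19, 0.11 and 0.17 after centring on sample medians. The assay rno-miR-598-5p turned to 0.96 and miR-421 to -0.60 with undetermined values set above the highest, and HSA-MIR-421 (B) to -0.59 with late readings kept. None of these passed after the change, and the cause was not tested.

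In camera, 0 lists passed under any setting tried on all samples, and leaving out a sample gave 0 to 1, the endothelial and mural list without C57BL/6J replicate 3. The strain difference in the number of assays detected per sample ranged from 54.7 to 83.2 when a sample was left out. With at least 2 of 3 samples, 94 assays were detected in 1 strain only, 84 in BTBR and 10 in C57BL/6J. For the controls, the 4 earliest spots moved the difference to -0.0651 for U6 rRNA, -0.0532 for snoRNA202, -0.39 for U87 and -0.24 for Y1. The mean of detected spots moved it to -1.19 for U6 rRNA, -0.59 for U87 and -2.27 for Y1. The median change without 1 sample ranged from -1.28 to -0.9995. The correlation with the authors' deposited fold changes was 1 over assays detected in all 6 samples, where both are the same difference of group means. In the simulated data, which held no shift of the whole panel, 15.3% of changes of 1 cycle were recovered. On the authors' values, which hold such a shift, some changes of that size passed, such as miR-146a at -0.99 and miR-30a-5p at -1.01. The simulated share therefore does not carry over to that comparison.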

Other observations

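The test of hairpin arms was planned before its result was seen. Outside the fixed lists, further miRNAs fell on the authors' values, here chosen after their values were seen. Both arms of the miR-1839 hairpin were among them, MMU-MIR-1839-3P with a log2 change of -2.03 (standard error 0.33) and MMU-MIR-1839-5P with -2.15 (0.45), which were -1.03 and -1.19 on the global mean scale. The related hsa-miR-15a (-2.13) and hsa-miR-15b (-1.73) fell together, with -1.07 and -0.82 on the global mean scale, as did both strands of miR-130b, hsa-miR-130b (-2.01) and mmu-miR-130b# (-2.38). The assay mmu-miR-130b# had 2 BTBR values, its other BTBR sample being undetermined. The muscle-enriched hsa-miR-1 fell as well (-1.37 relative to the median of the panel, -1.08 on the global mean scale), while the assay rno-miR-1 did not pass (log2 change -2.54, standard error 0.83). Both miR-532 arms fell, hsa-miR-532-3p with -1.77 and rno-miR-532-5p with -2.17, and were at -1.21 and -1.91 on the global mean scale, where 0 of these assays passed over all assays. A further assay, hsa-miR-532 (001518), did not pass (-1.05, standard error 0.38).

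Both arms of a hairpin come from 1 precursor, so a strain difference in the precursor would move them together. Assays were paired by name, and a strand made from several precursors can be paired with the other strand of only 1. The pair of hsa-miR-24 and mmu-miR-24-2#, whose name carries a copy number, is an example. For such pairs the premise holds only in part. Across 27 hairpins with both arms tested, the changes on the global mean scale relative to the median had Spearman rho = 0.24 (permutation p = 0.229) and Pearson r = 0.03 (permutation p = 0.858). Without the 2 hairpins farthest from the median, r was 0.21. The 95% bootstrap interval of rho ran from -0.23 to 0.64, so a shared strain difference may or may not be present, and these 27 hairpins do not decide; the planned bound, a p of 0.05 or more, was wrong as a sign of no relation, since a missed threshold excludes none. These are correlations across hairpins, which are not independent replicates.

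The medians of the log2 change were -1.03 for the 156 tested assays of pool A, with 54 past the threshold, and -1.19 for the 75 of pool B, with 31 past it. The mean raw threshold over the assays detected in all 6 samples was 22.1 ± 0.401 cycles in C57BL/6J and 21.7 ± 0.343 in BTBR (SD, n = 3 each, exact permutation p = 0.4). The spread between spots of a control, averaged over the 5 controls, was 4.88 ± 0.43 cycles in C57BL/6J and 3.11 ± 1.25 in BTBR (exact permutation p = 0.1).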
